A study of Rana omeimontis with 6 samples.

How the data were processed

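Liver RNA of Rana omeimontis tadpoles was measured in 6 libraries, 3 from before and 3 from after ontogenetic fat accumulation, per the labels. Per the labels' protocols total RNA was extracted with Trizol, mRNA was taken up on poly-T beads and fragmented, cDNA was primed with random hexamers and made into size-selected libraries, and these were sequenced as paired-end reads on an Illumina HiSeq instrument. The authors deposited a single matrix of FPKM values, fragments scaled for transcript length and for the mapped total, with 1 column per library and, per the file headers, the description of a matching protein for each transcript cluster. The assembler, the aligner, the program that computed FPKM and their versions are not given in the sources used here. No reference genome or gene annotation was used, so genes have no coordinates here.

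FPKM are not counts, so no count model was fitted. All 121726 features entered the summed FPKM, and every column of per-sample values was used. Features with at least 1 FPKM in at least 3 of the 6 libraries were kept, which left 40548, of which 14725 carried a protein description. The low values were inspected for the worth of 1 fragment: over features with values of 0.25 to 1.5 FPKM, the most frequent log2 ratio to after replicate 1 was read from a smoothed density. This gives the relative depth of the libraries only. As transcript lengths were not given in the sources used here, the number of fragments behind a value is unknown, no counting interval can be given, and low values are the least precise.

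Gene symbols were assigned by matching the protein names in the descriptions to the 918 symbols of 30 gene lists. The lists were written before the data were examined, and the name matches were fixed before any comparison of the stages was fitted. Of the 918 symbols 735 matched a feature and 634 were measured after the filter, by 911 features. Where several features carried a symbol, the one with the highest mean FPKM stood for the gene. Descriptions whose entries came only from rodents or humans (198 kept features) or only from listed non-vertebrate genera (127 kept features) gave no symbol. A gene split over several clusters, and close relatives such as the trypsins, can share reads, so that the level of a single feature is uncertain. The matrix carried no pathway terms, and no term test was run.

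The stages were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with lmFit and eBayes with a trend, two-sided, without covariates, and with Benjamini-Hochberg adjustment over all features. The threshold was an adjusted p of 0.05. Differences are after minus before. Gene lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, and again with a correlation estimated from the residuals and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. No list passed with an estimated correlation. The lowest adjusted p there was 0.0929, for fatty acid oxidation and for cholesterol synthesis and uptake. For each list the members past the threshold were also counted adjusted over the list alone. Per-library measures were compared with exact permutation tests, two-sided, in scipy 1.17.1 under Python 3.11.15, for which 0.1 is the smallest p at 3 against 3. Groups of 3 were not tested for outlying libraries.

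Named genes followed a rule fixed before the data were examined: the 10 largest increases and the 10 largest decreases among genes with an adjusted p under 0.05, no overlap between the stages and a mean of at least 10 FPKM in the higher stage, up to 3 genes per list with the smallest p past the threshold, and 15 genes chosen in advance whatever their result. A gene named outside this rule is said to be so. Some genes that the rule takes are not reported here.

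The fit and the list test were checked on simulated values with the real means and spreads. In a simulation of the comparison over 40548 features, 50 changed features at each size gave 6% recovered at a log2 change of 1, 60% at 2, 74% at 3 and 86% at 4, and 9 unchanged features were called among 122 calls. A raised list was called and 0 of 30 unchanged lists were. The simulated noise was independent between features, so this does not check the list test for genes that vary together. No libraries held identical values. Alternatives fixed before the data were examined covered pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, rescaling to equal totals, median-of-ratios factors, quantile normalization, a trimmed mean of log ratios coded by hand, eBayes without trend or with robust settings, library weights, a minimum absolute log2 fold change of 1, FPKM summed over the features of a symbol, the replicate number as a block, and leaving out each library. Rescaling each library without the pancreas-marker features was added after seeing the data.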

Results

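Liver transcripts of tadpoles of the frog Rana omeimontis were compared across a stage of larval life at which, per the labels, fat accumulates as part of ontogeny. The series asks how hepatic fat accumulation relates to somatic growth and to energy metabolism based on lipids. It holds 6 liver libraries, 3 from before and 3 from after fat accumulation, each a poly-A selected, paired-end RNA-seq library. The measurement is the FPKM of 121726 transcript clusters, here called features, of which 37708 carried the description of a matching protein. Summed FPKM per library lay between 1358660 and 1442120. Read totals were not given in the sources used here, so the absolute depth is unknown. The most frequent ratio of low FPKM values to those of after replicate 1 was 1.03 to 1.07 in the other 5 libraries, a measure of relative depth. The labels do not say whether the libraries came from separate animals, so the p-values below measure only the spread between these samples, which may be technical.

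Libraries of the same stage resembled each other more than libraries of different stages. Over 40548 features with at least 1 FPKM in at least 3 libraries, Pearson's r on the log2 scale, across features that are not independent replicates, was 0.838 to 0.867 for the 6 pairs within a stage and 0.727 to 0.775 for the 9 pairs between stages. The first principal component held 41.6% of the variance and separated the stages, with scores from 67.3 to 108 after and from -100 to -78.5 before fat accumulation. Features at 1 FPKM or more numbered 39278 ± 1827 after and 43669 ± 4932 before (SD, n = 3 each, exact permutation test, two-sided, p = 0.3, where 0.1 is the smallest p that 3 against 3 libraries can give). Before replicate 3 stood highest at 49148, and without it the difference between the stages was -1652 features, against -4391 with it. The 10 most abundant features took 29.5% ± 3.39 of the summed FPKM after and 29.5% ± 4.96 before (n = 3 each, exact permutation test, p = 1), and the 100 most abundant took 57.8% ± 2.44 and 59.0% ± 4.83 (n = 3 each, exact permutation test, p = 0.8). Features whose descriptions came only from non-vertebrate genera took 0.244% ± 0.0690 after and 0.132% ± 0.0210 before (n = 3 each, exact permutation test, p = 0.1, the smallest possible).

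After fat accumulation many transcripts for making, storing and oxidizing lipid, and for making cholesterol, were higher. SCD, the desaturase that makes monounsaturated fatty acids, rose from 1.38 ± 0.695 to 120 ± 36.5 FPKM. The feature that stood for PLIN2, a coat protein of lipid droplets, rose from 6.78 ± 1.89 to 83.1 ± 37.996. A feature described by an older name of PLIN2, unmatched to a symbol and named after its values were seen, rose from 6.02 ± 1.66 to 320 ± 102. HMGCS1, an early enzyme of the mevalonate pathway, rose from 2.88 ± 0.664 to 65.5 ± 0.705, and FABP1, the liver fatty acid-binding protein, from 1710 ± 321 to 10681 ± 278. Transcripts that fell included enzymes of amino acid breakdown. OAT, the ornithine aminotransferase, went from 512 ± 113 to 103 ± 27.3 FPKM and TDH from 13.1 ± 1.79 to 0.933 ± 0.582. All values are means ± SD of 3 libraries, and fold changes are after minus before on the log2(FPKM + 1) scale, which understates the change of low genes.

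Of the 40548 features tested, 1882 were higher and 1620 lower after fat accumulation (limma, Benjamini-Hochberg adjusted p under 0.05), 8.64% in all, and 10788 had an unadjusted p under 0.05. Among the features past the threshold, 929 of the higher and 498 of the lower had a protein description, and 494 and 459 changed by at least 2 on the log2 scale. The stages did not overlap in any of these 3502 features, nor in 32.5% of all tested, where chance gives 10%. The number past the threshold fell with any library left out, to 1867 without after replicate 1, 764 without after replicate 2, 691 without after replicate 3, 853 without before replicate 1, 1350 without before replicate 2 and 1773 without before replicate 3. Genes of 30 lists written before the data were examined were matched to features by protein name, and 634 could be measured. Of 74 genes named by a fixed rule, 70 passed the threshold and 27 of these did so without each library in turn.

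**Figure D1:**
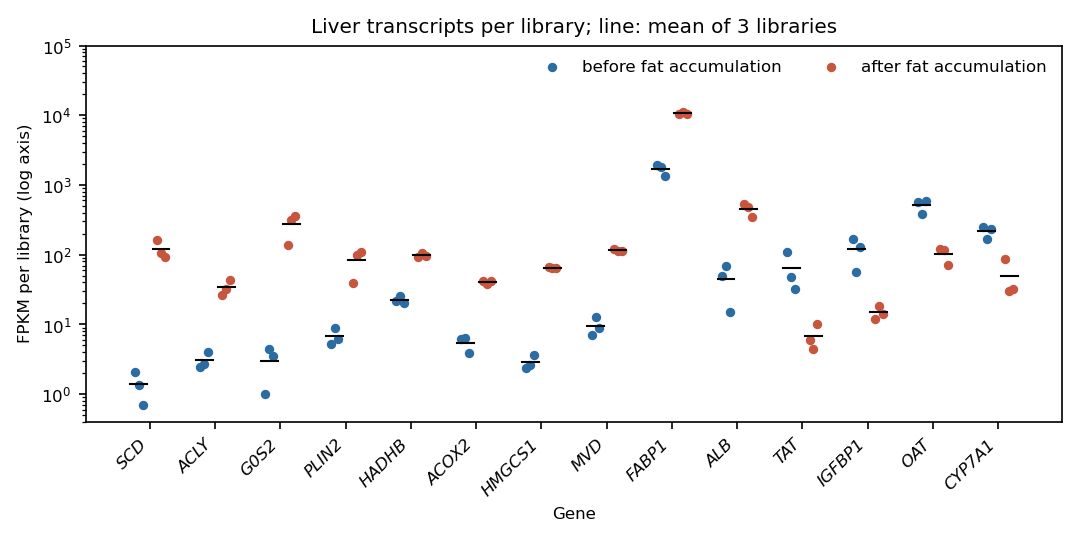
FPKM per library on a log axis for 14 named genes; each point is 1 library, blue before and red after fat accumulation, and black lines are means of 3 libraries. The 14 genes were picked among features past the threshold, none of which had overlapping stages, so their lack of overlap follows from that choice. The first 10, from SCD to ALB, were higher after, and TAT, IGFBP1, OAT and CYP7A1 were lower.

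Fatty acid synthesis and desaturation rose as a list. Of 14 measured members 6 rose and 2 fell, or 7 and 2 adjusted over the list alone, with a median log2 fold change of 1.17 (camera, adjusted p = 0.00412, and adjusted p = 0.257 with an estimated correlation). SCD had a log2 fold change of 5.67 ± 0.315 (SE, adjusted p = 0.00163). ACLY, which supplies cytosolic acetyl-CoA, rose from 3.07 ± 0.860 to 34.01 ± 8.91 FPKM (3.09, adjusted p = 0.00418), and ELOVL5, an elongase of polyunsaturated fatty acids, from 3.23 ± 0.441 to 14.8 ± 3.72 (1.88, adjusted p = 0.0119). The 2 members that fell, named after their values were seen, were MLXIPL, a carbohydrate-sensing transcription factor, at -1.40, and OXSM, of mitochondrial fatty acid synthesis, at -1.29. The feature that stood for FASN, the fatty acid synthase, lay below the filter, with 0.36 to 1.43 FPKM after and 0 to 0.09 before, and gave no test. Features with unmatched descriptions may also belong to FASN, so the level of the gene is uncertain. ELOVL5 missed the threshold without after replicate 3 (adjusted p = 0.0570).

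Triacylglycerol synthesis and lipid droplet genes gave 4 increases and no decrease among 14 measured members, the same count when adjusted over the list alone, with a median of 0.66 (camera, adjusted p = 0.000428, and adjusted p = 0.257 with an estimated correlation). G0S2, an inhibitor of the main triacylglycerol lipase, rose from 3.01 ± 1.77 to 272 ± 118 FPKM (6.09 ± 0.499 SE, adjusted p = 0.00363), the largest increase of all genes with a symbol at the pseudocount of 1. At a pseudocount of 0.1 the ACSL5 increase was larger, 8.22 against 6.56 for G0S2. The feature that stood for PLIN2 rose by 3.33 (adjusted p = 0.009999), and the unmatched feature with its older name by 5.50 (limma, adjusted p = 0.00163). FITM2, which takes part in droplet formation, rose from 0.650 ± 0.165 to 7.10 ± 0.419 (2.30, adjusted p = 0.00533). DGAT2, an enzyme of the last step of triacylglycerol synthesis, measured 5.78 ± 2.15 after and 4.15 ± 4.57 before (0.70, adjusted p = 0.513). Lipases did not pass as a list (camera, adjusted p = 0.806). Of 9 measured, DAGLA and CES1 rose and LIPG fell, while adjusted over the list alone 2 rose and 2 fell. That list had a median of 0.25, a mean of -0.02 and an upward test. PNPLA2, the main triacylglycerol lipase, measured 0.660 ± 0.125 after and 3.40 ± 1.70 before (-1.32, adjusted p = 0.0743). It passed without before replicate 2 (adjusted p = 0.0415) and with FPKM summed over the features of a symbol (adjusted p = 0.0195), in a range up to 0.194 over the alternatives. LIPG (21.7 ± 2.90 to 6.46 ± 1.25 FPKM) lost its call without after replicate 2 or before replicate 1 (adjusted p = 0.0513 and 0.0549). DAGLA and CES1 lost theirs in all 6 fits with 1 library left out, with adjusted p up to 0.104 without before replicate 1 and 0.120 without after replicate 3.

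Fatty acid oxidation rose as a list. Of 24 measured members 16 rose and 0 fell (17 and 0 adjusted over the list alone), the median was 1.18, and 20 had stages that did not overlap, against 32.5% of all features tested and 10% by chance (camera, adjusted p = 6.36e-14, and adjusted p = 0.0929 with an estimated correlation). HADHB of the mitochondrial trifunctional protein rose from 22.5 ± 2.91 to 98.4 ± 6.27 FPKM (2.08, adjusted p = 0.00363). The peroxisomal enzymes ACOX2, from 5.48 ± 1.35 to 40.9 ± 2.56, and ACAA1, from 7.34 ± 1.58 to 34.5 ± 4.76, rose by 2.71 (adjusted p = 0.00371) and 2.10 (adjusted p = 0.00648). ACSL5, an acyl-CoA synthetase, was listed at 0 in before replicates 1 and 2 and at 0.1 in before replicate 3, against 9.11, 70.5 and 80.9 after (5.24, adjusted p = 0.0154). PPARA, the nuclear receptor that drives oxidation genes, rose from 2.55 ± 0.911 to 10.2 ± 3.01 (1.66, adjusted p = 0.0244). Without 1 library, ACSL5 and PPARA each lost the call in 5 of 6 fits, at adjusted p up to 0.0583 (without after replicate 2) and 0.0853 (without before replicate 1). The feature that stood for CPT1A lay below the filter at 0.2 to 0.48 FPKM after and 0.46 to 0.68 before. Features with unmatched descriptions may also belong to the gene, so its level is uncertain.

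Lipid transport and apolipoprotein genes gave 3 increases and no decrease among 19 measured members (4 and 0 adjusted over the list alone). The list had a median of 0.41 (camera, adjusted p = 0.00625, and adjusted p = 0.257 with an estimated correlation). Without before replicate 3 the camera adjusted p was 0.0741, in a range of 0.000543 to 0.0741 over the alternatives. The increases were FABP1 (2.66 ± 0.163 SE, adjusted p = 0.00214), SLC27A2, a very long-chain acyl-CoA synthetase, from 5.92 ± 0.738 to 21.7 ± 1.17 FPKM (1.72, adjusted p = 0.00731), and APOF. APOF lost its call in all 6 fits with 1 library left out, with adjusted p up to 0.110 without after replicate 3. APOB, the main protein of very low density lipoprotein, measured 331 ± 33.97 after and 279 ± 75.7 before (0.27, adjusted p = 0.475). Among 6 measured genes of ketone body metabolism BDH1 and AACS rose and 0 fell (3 and 0 adjusted over the list alone, camera, adjusted p = 0.126). Without a filter the ketone list passed (adjusted p = 0.0417, in a range up to 0.363 over the alternatives). BDH1 went from 9.28 ± 2.79 to 31.7 ± 5.27 (1.69, adjusted p = 0.0167). It lost the call in 3 of 6 fits with 1 library left out, with adjusted p up to 0.0691 without after replicate 2. AACS lost it in all 6, up to 0.129 without the same library.

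Cholesterol synthesis and uptake had the highest median of the 30 lists, 1.82. Of 20 measured members 17 rose and 0 fell, and adjusted over the list alone 17 rose and 1 fell (camera, adjusted p = 3.34e-16, and adjusted p = 0.0929 with an estimated correlation). HMGCS1 rose by 4.11 ± 0.199 (SE, adjusted p = 0.00163). MVD, which makes isopentenyl diphosphate, rose from 9.58 ± 2.94 to 116 ± 5.87 FPKM (3.502, adjusted p = 0.00222), and MSMO1, a sterol C4-demethylase, from 4.57 ± 2.05 to 98.2 ± 22.9 (4.21, adjusted p = 0.00382). These 3 passed without each library in turn. Of 6 measured bile acid genes 4 did not pass, and the list did not pass with camera, with a median of 0.44 (adjusted p = 0.109, but higher with fry, adjusted p = 0.0144). HSD3B7 rose from 11.2 ± 0.797 to 52.7 ± 1.01 (2.13, adjusted p = 0.00313), and CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell from 218 ± 45.4 to 49.9 ± 32.8 (-2.26, adjusted p = 0.0272), with 1 higher and 1 lower adjusted over the list alone too. CYP7A1 passed only without after replicate 1 among the fits with 1 library left out, with adjusted p up to 0.0936 without after replicate 3.

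**Figure D2:**
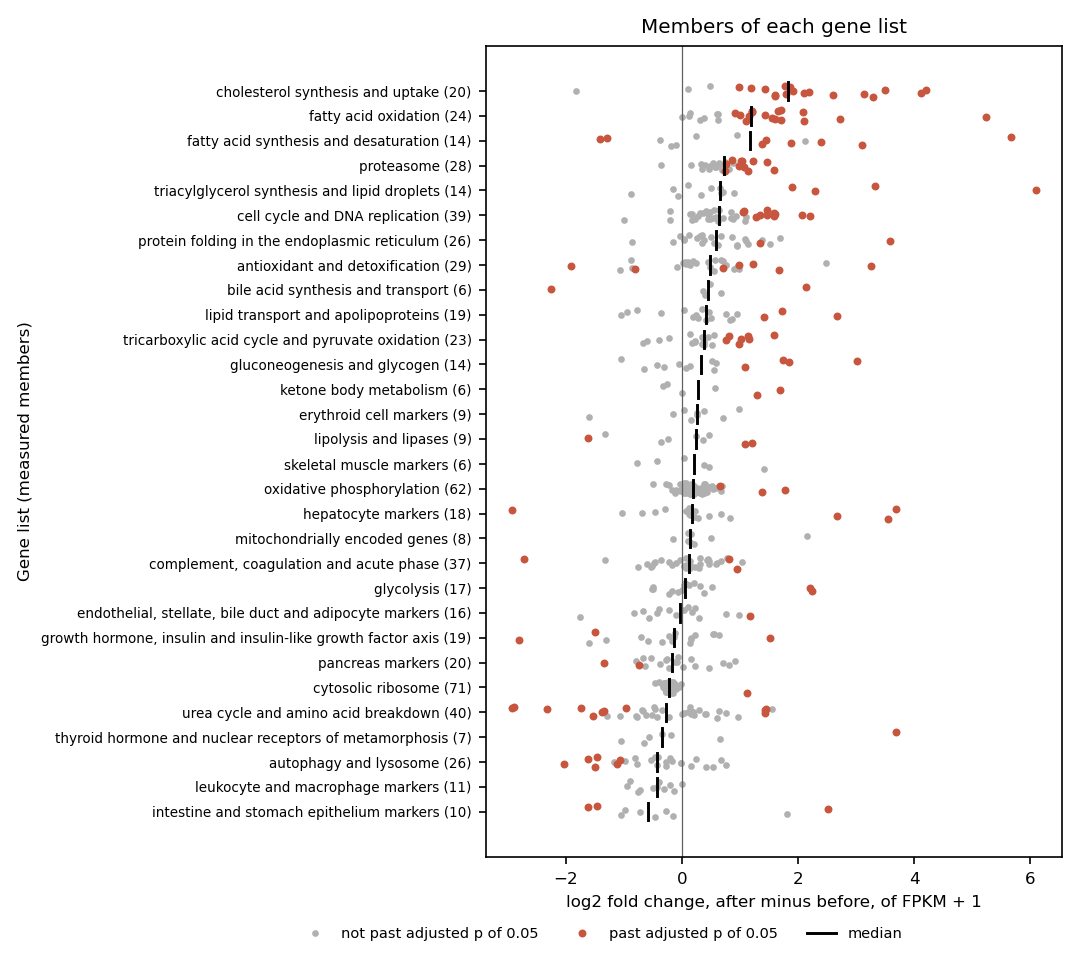
The log2 fold change, after minus before, of every measured member of the 30 gene lists, with the number measured in brackets; red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. Cholesterol synthesis stands at a median of 1.82, fatty acid oxidation at 1.18 and fatty acid synthesis at 1.17.

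Glycogen genes held several of the increases in carbohydrate metabolism. Of 14 measured genes of gluconeogenesis and glycogen 4 rose and 0 fell (4 and 2 adjusted over the list alone, camera, adjusted p = 0.126). Without a filter that list passed (adjusted p = 0.0341, in a range up to 0.225 over the alternatives). PYGL, the liver glycogen phosphorylase, rose from 42.3 ± 7.58 to 141 ± 9.75 FPKM (1.73, adjusted p = 0.00695), PPP1R3C, a glycogen-targeting phosphatase subunit, from 5.78 ± 0.720 to 61.0 ± 33.2 (3.01, adjusted p = 0.0168), while its relative PPP1R3B was listed at 0, 0 and 0.18 before and at 2.54, 2.06 and 3.99 after (1.84, adjusted p = 0.0168). PYGL held without each library, PPP1R3C only without after replicate 1, with adjusted p up to 0.0659 without after replicate 2, and PPP1R3B in 3 of 6 fits, up to 0.0641 without before replicate 1. Glycolysis did not pass as a list (17 measured, 2 rose and 0 fell on both adjustments, over all features and adjusted over the list alone, camera, adjusted p = 0.298). Its 2 increases were LDHA, from 25.2 ± 11.99 to 114 ± 26.3 (adjusted p = 0.0184), and ENO3, from values of 0.71 to 2.17 FPKM before to a mean of 10.5 ± 3.37 after (2.24, adjusted p = 0.0157). Without after replicate 3 these reached adjusted p of 0.0742 and 0.0635, the highest over the fits with 1 library left out.

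Genes of the tricarboxylic acid cycle and pyruvate oxidation rose in 7 of 23 measured cases and fell in 0 (8 and 1 adjusted over the list alone). The list had a median of 0.38 (camera, adjusted p = 0.000124, and adjusted p = 0.586 with an estimated correlation). SUCLA2 rose from 6.003 ± 0.823 to 20.2 ± 3.53 FPKM (1.59, adjusted p = 0.0126), and PDHA1 and DLAT of the pyruvate dehydrogenase complex rose by 1.15 (adjusted p = 0.0153) and 0.98 (adjusted p = 0.0247). With 1 library left out these 3 lost their calls in 3, 3 and 6 of 6 fits, with adjusted p up to 0.0568 without after replicate 3 for SUCLA2, and 0.0703 and 0.0973 without after replicate 2 for PDHA1 and DLAT. Oxidative phosphorylation had a median of 0.19, or 0.12 to 0.27 over other scalings. Of its 62 measured members 3 rose and 0 fell (1 and 0 adjusted over the list alone, camera, adjusted p = 0.000206, and adjusted p = 0.718 with an estimated correlation). Without before replicate 1 the camera adjusted p was 0.0753, the highest in a range from 6.76e-08 over the alternatives. CYCS, cytochrome c, rose from 91.5 ± 19.2 to 315 ± 66.4 (1.77, adjusted p = 0.009999) and held without each library. COX4I1 (20.7 ± 5.48 to 56.6 ± 21.3) and NDUFC2 (78.7 ± 5.38 to 125 ± 10.9) lost their calls in all 6 such fits, with adjusted p up to 0.132 without before replicate 1 and 0.160 without after replicate 2. None of 8 mitochondrially encoded genes passed, over all features or adjusted over the list alone (median 0.14, or 0.19 to 0.23 over other scalings, camera, adjusted p = 0.126), although without after replicate 3 the camera adjusted p was 0.00385, the lowest in a range up to 0.434 over the alternatives.

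Several enzymes of amino acid breakdown fell. Of 40 measured genes of the urea cycle and amino acid breakdown 8 fell and 3 rose (11 and 5 adjusted over the list alone), with a median of -0.28. The list itself did not pass (camera, adjusted p = 0.225), except with quantile normalization (adjusted p = 0.0217, in a range up to 0.402 over the alternatives). OAT fell by 2.32 on the log2 scale (SE 0.271, adjusted p = 0.00843), TDH, a threonine dehydrogenase, by 2.90 (adjusted p = 0.00533), and TAT, the tyrosine aminotransferase, from 63.7 ± 41.7 to 6.85 ± 2.99 FPKM (-2.92, adjusted p = 0.0206). KYNU, of tryptophan breakdown, rose from 7.73 ± 0.321 to 22.5 ± 2.21 (1.42, adjusted p = 0.0106). TDH and OAT passed without each library in turn. KYNU missed the threshold without after replicate 3 (adjusted p = 0.0512), and TAT in 4 of 6 fits, with adjusted p up to 0.0744 without after replicate 2.

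Genes of cell cycle and DNA replication were higher as a list. In the list of cell cycle and DNA replication 11 of 39 measured members rose and 0 fell (16 and 1 adjusted over the list alone). Its median was 0.64 (camera, adjusted p = 6.45e-10, and adjusted p = 0.384 with an estimated correlation). MCM3 and MCM5, subunits of the replicative helicase, rose from 1.98 ± 0.340 to 12.8 ± 1.06 FPKM (2.21, adjusted p = 0.00515) and from 2.81 ± 0.505 to 14.9 ± 1.08 (2.07, adjusted p = 0.00582). PCNA, the sliding clamp of DNA polymerase, rose from 35.2 ± 6.21 to 106 ± 7.80 (1.58, adjusted p = 0.00854). All 3 held without each library.

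Proteasome genes were higher as a list, and genes of autophagy and lysosome were lower as a list. Of 28 measured proteasome genes 11 rose and 0 fell (22 and 0 adjusted over the list alone). The proteasome list had a median of 0.72 (camera, adjusted p = 1.95e-12, and adjusted p = 0.446 with an estimated correlation), with PSMA3 going from 20.6 ± 2.34 to 63.2 ± 3.66 FPKM (1.58, adjusted p = 0.00700). PSMA2 and PSMB5 rose by 1.14 (adjusted p = 0.0125) and 1.08 (adjusted p = 0.0158). Each lost the call in 3 of 6 fits with 1 library left out, with adjusted p up to 0.0617 and 0.0704 without after replicate 2. Of 26 measured genes of autophagy and lysosome 6 fell and 0 rose (7 and 1 adjusted over the list alone). The list had a median of -0.42 (camera, adjusted p = 0.0125, and adjusted p = 0.632 with an estimated correlation). Without after replicate 1 the camera adjusted p was 0.0816, the highest in a range from 0.00272 over the alternatives. Markers of leukocytes and macrophages, cells rich in lysosomes, were lower as a list by a similar amount, with a median of -0.43 (camera, adjusted p = 0.0338, and adjusted p = 0.632 with an estimated correlation). None of the 11 measured markers passed singly, and the list call was lost without after replicate 1 or before replicate 2. The origin of either decrease was not tested. The 6 that fell included MAP1LC3B, a component of the autophagosome membrane, from 127 ± 31.5 to 41.7 ± 15.5 (-1.62, adjusted p = 0.0267), BECN1 from 18.2 ± 6.44 to 4.03 ± 2.56 (-2.04, adjusted p = 0.0446), ATG14 from 6.20 ± 0.748 to 1.55 ± 0.206 (-1.49, adjusted p = 0.0156) and the lysosomal CTSA from 15.2 ± 1.79 to 6.52 ± 1.34 (-1.11, adjusted p = 0.0307). With 1 library left out these lost their calls in 5, 6, 3 and 6 of 6 fits, with adjusted p up to 0.0923, 0.118, 0.0654 and 0.106, without after replicate 2, before replicate 3, after replicate 3 and before replicate 1 respectively.

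Genes of protein folding in the endoplasmic reticulum, which include chaperones and the sensors and transcription factors of its stress response, were higher as a list, with 2 increases and 0 decreases among 26 measured members (7 and 0 adjusted over the list alone). The list had a median of 0.58 (camera, adjusted p = 3.46e-05, and adjusted p = 0.632 with an estimated correlation). HSPA5, the main chaperone there, rose from 23.1 ± 26.7 to 195 ± 43.0 FPKM (3.59, adjusted p = 0.0315), and DNAJC3 from 10.8 ± 3.04 to 28.5 ± 5.17 (1.34, adjusted p = 0.0286). Both passed only without before replicate 3 among the fits with 1 library left out, and reached adjusted p of 0.107 and 0.104 without after replicate 3. Pancreatic enzyme transcripts were abundant in every library, and which cells carried these changes was not tested. Cytosolic ribosomal protein genes had a median of -0.22 over 71 measured members, or -0.17 to -0.09 over other scalings (camera, adjusted p = 2.14e-05, and adjusted p = 0.718 with an estimated correlation). Only FAU of that list passed, as an increase of 1.12 (adjusted p = 0.0481), and 0 passed adjusted over the list alone. FAU held only without after replicate 2, with adjusted p up to 0.149 without after replicate 3.

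In the growth hormone, insulin and insulin-like growth factor axis IGFBP1, a binding protein of insulin-like growth factors, fell from 119 ± 58.3 to 14.8 ± 3.41 FPKM (-2.80, adjusted p = 0.0159) and SOCS3, a feedback inhibitor of cytokine signalling, from 24.6 ± 9.68 to 7.99 ± 2.74 (-1.49, adjusted p = 0.0473). IGFBP4 rose from 2.34 ± 0.759 to 8.58 ± 2.23 (1.52, adjusted p = 0.0301). With 1 library left out IGFBP1, SOCS3 and IGFBP4 lost their calls in 4, 6 and 5 of 6 fits, with adjusted p up to 0.0653, 0.137 and 0.104, each without after replicate 3. The 19 measured members did not pass as a list (1 higher and 2 lower on both adjustments, over all features and adjusted over the list alone, camera, adjusted p = 0.557). GHR, the growth hormone receptor, measured 1.74 ± 0.414 after and 2.07 ± 0.0416 before (-0.18, adjusted p = 0.688). The feature that stood for IGF2 lay below the filter, with 0.3 to 0.61 FPKM after and 0 to 0.18 before. For IGF1, LEPR and THRB no feature matched. Of 7 measured genes of thyroid hormone action and metamorphosis TTR, a carrier of thyroid hormone, rose from 111 ± 59.9 to 1258 ± 142 (3.69, adjusted p = 0.0108) and 0 fell (2 and 2 adjusted over the list alone). The list did not pass (camera, adjusted p = 0.806), with a mean of 0.22, a median of -0.35 and a downward test.

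The list of antioxidant and detoxification genes was higher, and 5 of 29 measured members rose and 2 fell (15 and 4 adjusted over the list alone). The list had a median of 0.49 (camera, adjusted p = 0.000428, and adjusted p = 0.257 with an estimated correlation). GSTT1, a glutathione transferase, rose from 58.3 ± 8.61 to 580 ± 163 FPKM (3.26, adjusted p = 0.00317) and MGST3, a microsomal glutathione transferase, from 260 ± 31.5 to 602 ± 13.3 (1.22, adjusted p = 0.00877), while HMOX1, the heme oxygenase, fell from 38.6 ± 15.8 to 9.25 ± 2.67 (-1.91, adjusted p = 0.0239). HMOX1 passed only without before replicate 3 among the fits with 1 library left out, with adjusted p up to 0.0778 without after replicate 2. In the list of complement, coagulation and acute phase SAA1, serum amyloid A, fell from 1638 ± 1144 to 219 ± 60.5 (-2.72, adjusted p = 0.0209), and AMBP and MASP2 rose by 0.95 (adjusted p = 0.0235) and 0.82 (adjusted p = 0.0455). The 37 measured members did not pass as a list (2 higher and 1 lower, or 2 and 3 adjusted over the list alone, camera, adjusted p = 0.272). Without before replicate 1, though, the camera adjusted p was 0.0387, the lowest in a range up to 0.993 over the alternatives. With 1 library left out SAA1, AMBP and MASP2 lost their calls in 4, 5 and 6 of 6 fits, with adjusted p up to 0.0758 and 0.0763 without after replicate 2 and 0.145 without after replicate 3.

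Hepatocyte markers moved in both directions. ALB, albumin, rose from 44.97 ± 27.8 to 456 ± 94.7 FPKM (3.54, adjusted p = 0.0163), along with TTR and FABP1, while TAT fell. Over 18 measured markers the median was 0.17, and 4 rose and 2 fell adjusted over the list alone (camera, adjusted p = 0.108). Without before replicate 1 or before replicate 3 that list passed (adjusted p = 0.0349 and 0.0353), in a range of 0.0341 to 0.279 over the alternatives. ALB lost its call in 3 of 6 such fits, with adjusted p up to 0.0630 without after replicate 2. Globins were abundant. HBB, named after its values were seen, measured 13738 ± 1682 after and 10659 ± 1665 before (adjusted p = 0.204). None of 9 erythroid markers passed, and 1 was lower adjusted over the list alone (camera, adjusted p = 0.272). Without a filter the erythroid list passed as higher (adjusted p = 0.0251, in a range up to 0.581 over the alternatives). None of 11 leukocyte and macrophage markers passed either, and 2 were lower adjusted over the list alone, but as a list they were lower, with a median of -0.43 (camera, adjusted p = 0.0338, and adjusted p = 0.632 with an estimated correlation). The list of leukocyte and macrophage markers lost that call without after replicate 1 (adjusted p = 0.195) and without before replicate 2 (adjusted p = 0.154), and also with median-of-ratios scaling (adjusted p = 0.0836) or rescaled without the pancreas markers (adjusted p = 0.0633), a range of 0.00544 to 0.195 over all settings. COL1A2, a collagen chain, rose from 8.003 ± 2.58 to 18.8 ± 2.95 (1.17, adjusted p = 0.0442), the only one of 16 endothelial, stellate, bile duct and adipocyte markers past the threshold (2 higher and 1 lower adjusted over the list alone; median -0.04, or -0.09 to 0.04 over other scalings, with an upward test, camera, adjusted p = 0.984). It lost its call in all 6 fits with 1 library left out, up to an adjusted p of 0.134 without after replicate 3. Of 6 skeletal muscle markers 0 passed, over all features or adjusted over the list alone (median 0.21 with a downward test, camera, adjusted p = 0.988).

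Transcripts of pancreatic digestive enzymes were the most abundant in every library. All features matched to pancreas markers together took 28.9% ± 4.39 of the summed FPKM after and 29.0005% ± 6.22 before fat accumulation (n = 3 each, exact permutation test, two-sided, p = 1), ranging from 22.2% in before replicate 3 to 34.4% in before replicate 2. PRSS1, a trypsin, measured 184745 ± 29859 FPKM after and 166290 ± 31645 before (0.16, adjusted p = 0.629), and INS, insulin of the pancreatic islet, 59.9 ± 12.7 and 31.3 ± 7.68 (0.92, adjusted p = 0.0750). Both are named here after their values were seen. Of 20 measured markers CTRB2, a chymotrypsinogen, fell from 1810 ± 217 to 717 ± 99.1 (-1.34, adjusted p = 0.00908) and CLPS, colipase, from 5671 ± 1204 to 3342 ± 246 (-0.74, adjusted p = 0.0493), and adjusted over the list alone 1 rose and 3 fell (camera, adjusted p = 0.384). CLPS passed only without before replicate 3 among the fits with 1 library left out, with adjusted p up to 0.140 without after replicate 2. Without before replicate 3 the list as a whole was lower (adjusted p = 0.0254, in a range up to 0.943 over the alternatives). Among 10 measured markers of intestine and stomach epithelium SI, sucrase-isomaltase, rose from 20.4 ± 11.1 to 116 ± 35.9 (2.52, adjusted p = 0.0170), whereas VIL1 fell from 24.7 ± 4.02 to 8.62 ± 3.29 (-1.46, adjusted p = 0.0304) and SLC5A1 from 4.99 ± 1.11 to 0.987 ± 0.669 (-1.62, adjusted p = 0.0307), 1 higher and 2 lower adjusted over the list alone as well (camera, adjusted p = 0.364). SI, VIL1 and SLC5A1 lost their calls in 3, 5 and 5 of 6 such fits, with adjusted p up to 0.0665 and 0.101 without after replicate 3 and 0.103 without before replicate 1.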

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

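Among the alternatives, rescaling without the pancreas-marker features was chosen after seeing the data. With 1882 features higher and 1620 lower, the counts stayed within 1.5 times of these under every scaling, pseudocount and fit option except those named here. Without a filter 634 were higher and 433 lower among 111336 tested, and 44 of the 70 named genes passed. Leaving out 1 library gave 392 to 1184 higher, 299 to 917 lower, and 28 to 48 of the named genes past the threshold, in fits on fewer samples. No named gene changed direction under any setting run for it, and 44 of the 70 passed under all 8 settings other than the replicate block and the fits on fewer libraries. The share of higher calls moved from 53.7% to at most 59.4% with another scaling. Of the 14 lists past the threshold 0 passed with an estimated correlation and 12 lists passed with fry, and leaving out 1 library gave 12 to 15 lists.

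Whether the replicate numbers shared by the stages mark pairs is not known. Libraries with the same number had correlations of -0.00489, -0.0387 and -0.0876 between their deviations from the stage means. Those with different numbers had -0.0312 to 0.0674. Low correlations do not show that the libraries were unpaired in the design. With a replicate block 194 features were higher and 145 lower, 19 named genes and 14 lists passed, and the fit has fewer residual degrees of freedom.

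The share of the 10 most abundant features differed between the stages by 0.0318 percentage points, that of the 100 most abundant by -1.21 and of the 1000 most abundant by -0.505, and with 1 library left out the first ranged from -2.66 to 2.23. The cause was not tested. The first principal component held 35.7% at a pseudocount of 0.1, 38.3% with scaled features and 43.3% to 47.9% with 1 library left out, and separated the stages each time.

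Some lists that did not pass changed direction, and the cause was not tested. Complement, coagulation and acute phase turned downward with quantile normalization (adjusted p = 0.993). Skeletal muscle markers turned upward without a filter (0.881), with quantile normalization (0.993) and with the replicate block (0.944). Endothelial, stellate, bile duct and adipocyte markers turned downward with quantile normalization (0.893), summed FPKM (0.907) and fry (0.976). Over all 6 fits with 1 library left out, whichever the direction, adjusted p ranged from 0.667 to 0.949 for lipolysis and lipases, 0.0387 to 0.975 for complement, 0.0254 to 0.943 for pancreas, 0.409 to 0.943 for muscle, and 0.761 to 0.967 for endothelial and related markers. Those that turned among them had adjusted p of at least 0.619, and the 0.0387 and 0.0254 kept their direction. With fry 5 lists lost the call: oxidative phosphorylation (0.337), cytosolic ribosome (0.195), endoplasmic reticulum folding (0.181), leukocyte (0.0740) and autophagy (0.0633). Another 3 gained it: ketone body metabolism (0.0253), gluconeogenesis and glycogen (0.0252), and bile acid synthesis and transport (0.0144). Mitochondrially encoded genes passed with quantile normalization (0.0394) and rescaled without the pancreas markers (0.0477), and hepatocyte markers without a filter (0.0341). Depth in fragments is unknown, so how far it limits low features could not be measured.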

Other observations

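All groups, genes and tests of explanations in this part were chosen only after the results were seen. Among them, 3 groups of features of protein synthesis were higher after fat accumulation. They were picked by description, with 1 feature per description, so that a gene described in several ways counts more than once. Their camera p-values were adjusted over these 3 groups only. As the groups were picked from the same values, those p-values add no support. Cytosolic ribosomal protein genes, a list fixed in advance, did not rise with them. Their median was -0.22, against -0.0779 for all features, or -0.17 to -0.09 over other scalings (camera, adjusted p = 2.14e-05, and adjusted p = 0.718 with an estimated correlation). With fry that list did not pass (adjusted p = 0.195), and its only member past the threshold, FAU, rose. Of 20 features described as aminoacyl-tRNA ligases, the enzymes that charge tRNA, and not as mitochondrial, 13 rose and 0 fell, with a median log2 fold change of 1.78 (camera, adjusted p = 7.27e-10, and adjusted p = 0.212 with an estimated correlation). Methionyl-tRNA synthetase went from 2.53 ± 1.24 to 22.3 ± 5.65 FPKM and asparagine--tRNA ligase from 23.5 ± 5.67 to 113 ± 30.02 (SD, 3 libraries each). Of 68 features for mitochondrial ribosomal proteins 22 rose and 0 fell (median 0.69, adjusted p = 4.26e-19, or adjusted p = 0.212 with an estimated correlation), and of 28 for proteins of ribosome assembly and the nucleolus 9 rose and 0 fell (median 1.10, adjusted p = 1.20e-09, or adjusted p = 0.212 with an estimated correlation). Another 3 genes, picked singly and tested as no group, encode enzymes that make amino acids. Asparagine synthetase rose from 4.40 ± 0.834 to 68.1 ± 18.2 (3.65, limma, adjusted p = 0.00254), PYCR1, of proline synthesis, from 0.620 ± 0.688, with before replicate 2 listed at 0, to 17.2 ± 3.88 (3.56, adjusted p = 0.00622), and phosphoserine aminotransferase, of serine synthesis, from 5.18 ± 1.27 to 27.7 ± 6.21 (2.21, adjusted p = 0.00854). These 3 passed without each library in turn.

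Hepcidin, the hormone that limits iron export, fell from 1904 ± 777 to 19.1 ± 15.8 FPKM (-6.76 ± 0.571 SE, limma, adjusted p = 0.00391), and UCP3, a mitochondrial carrier, from 163 ± 74.2 to 1.91 ± 1.67 (-5.94, adjusted p = 0.00484). At the pseudocount of 1 both exceed in size every decrease among the genes with a symbol, and both passed without each library in turn. CYP24A1, which inactivates vitamin D, fell from 33.0 ± 16.5 to 1.87 ± 2.14 (-3.71, adjusted p = 0.0187), but passed in only 2 of 6 fits with 1 library left out. A feature described, with its first letter missing, as adipose differentiation-related protein, an older name of perilipin 2, rose from 6.02 ± 1.66 to 320 ± 102 (5.50, adjusted p = 0.00163). Its description matched no symbol, so a feature with a lower mean stood for PLIN2. Another feature, described as retinoid-binding protein 7, rose from 212 ± 22.3 to 1729 ± 782 (2.94, adjusted p = 0.00622). After replicate 1 measured 138 FPKM for G0S2, 39.5 for PLIN2, 9.11 for ACSL5 and 24.6 for PPP1R3C, the lowest of the 3 libraries after fat accumulation in each case. For SCD, ALB and retinoid-binding protein 7 it was instead the highest of the 3, at 161, 539 and 2618 FPKM.

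The higher fatty acid, lipid droplet and cholesterol genes, 43 of 72 measured members of 4 lists past the threshold with a median of 1.29, were set against 2 technical explanations. If a few abundant features had shifted the FPKM of all others, scaling should remove the rise. The lower of the medians under median-of-ratios scaling and under rescaling without the pancreas markers was 1.33, with an SD of 0.0467 over the fits with 1 library left out. The mean shares of the 10 most abundant features and of the pancreas markers differed by only 0.0318 and -0.0529 percentage points between the stages. These scalings moved the median of all features only from -0.0779 to -0.0219 and -0.0437. They had little to remove, so the 1.33 adds little beyond those shares. A larger hepatocyte share of the RNA would raise hepatocyte markers alike, yet the median of 18 of them was 0.17 with 95% order-statistic bounds of -0.30 and 0.67. The markers did not move alike. ALB, TTR and FABP1 changed by 3.54, 3.69 and 2.66, above 1.29, TAT by -2.92, and the other 14 did not pass. As markers can themselves change with the stage, their median cannot exclude a larger share. Of the 18, 12 are also in another list, and genes are not independent. The difference between the stages that the labels name stays a possible explanation, untested against age, feeding or time of sampling.

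With 3 libraries per stage, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split passed 3502 features and the highest of the others 20. For gene lists the real split passed 14 and the others 3 to 10. Camera at the preset correlation thus passed several lists under splits that mix the stages. A list call at that preset is weaker than its adjusted p reads. In each case 1 split, the real one, gave as many.

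Pancreatic enzyme transcripts in every library may come from pancreas tissue taken along with the liver. That explanation needs islet hormones as well, and the lowest value of INS, GCG and SST over the 6 libraries was 12.8 FPKM, with 19 of 20 measured pancreas markers at 1 FPKM or more in all 6. GCG and SST are also made in the gut, and expression of digestive enzymes by cells of the tadpole liver itself stays open. No biological explanation was tested. Which cells carried the changes in lists not particular to liver, such as folding, proteasome and cell cycle, was not tested either.

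Some single genes of inflammation and early response, picked because they fell and tested as no group, were lower after fat accumulation. Besides hepcidin, SAA1 and SOCS3, IER2 fell from 102 ± 12.1 to 18.8 ± 3.59 FPKM (-2.39, limma, adjusted p = 0.00417), JUNB from 32.9 ± 2.81 to 10.7 ± 1.25 (-1.54, adjusted p = 0.00917), FOS from 17.7 ± 9.46 to 1.63 ± 1.20 (-2.77, adjusted p = 0.0268) and IL1B from 14.4 ± 1.01 to 2.31 ± 1.46 (-2.33, adjusted p = 0.0190). FOS and IL1B passed in only 1 and 2 of 6 fits with 1 library left out, with adjusted p up to 0.0873 and 0.0705. The list of complement, coagulation and acute phase genes, fixed in advance, did not pass (median 0.13, or 0.01 to 0.20 over other scalings, camera, adjusted p = 0.272). The leukocyte and macrophage markers were lower as a list (median -0.43, camera, adjusted p = 0.0338, and adjusted p = 0.632 with an estimated correlation), but none of 11 passed singly. That list call was lost without after replicate 1 or before replicate 2. Median-of-ratios scaling and rescaling without the pancreas markers removed it too. CP and CRP did not pass, at 0.58 (adjusted p = 0.464) and -0.60 (adjusted p = 0.855).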
